A study of Mus musculus with 2 samples.

How the data were processed

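Small RNA was measured in the midbrain of mouse embryos of the B6NCrl strain at 15.5 days of development. Per the labels, the libraries held RNA under 30 bases, were made from tissue pooled over male and female embryos, and are biological replicates of the same tissue and age. Replicate 1 came from 78 embryos and replicate 2 from 62. The design therefore has 1 group of 2 replicates, and no contrast between groups exists for edgeR's quasi-likelihood test.

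The authors deposited, for each library, whole read counts per microRNA (miRNA) gene in 3 columns, without any normalization. The columns hold counts without regard to strand, counts on the sense strand of the gene and counts on the opposite strand. Per the deposited readme text, the reads were aligned to the mm10 assembly with GENCODE annotation M4. The aligner, the counter and their settings are not given in the sources used here. The row names and the column layout are those of STAR's gene counts, a format in which reads with several mapping places are tallied apart and given to no gene. The table has 1973 genes and 4 rows that name no gene. Those 4 rows hold unmapped reads, reads with several mapping places, reads outside the annotated genes and ambiguous reads. They were kept out of library sizes and tests. Their shares of all reads in replicate 1 and replicate 2 were 13.4% and 16.9% unmapped, 37.7% and 35.8% with several places, 3.57% and 3.43% outside genes on the sense strand, and 0% ambiguous.

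Gene symbols and coordinates came from GENCODE M21, which is on the same assembly (GRCm38, mm10). Of the 1973 identifiers, 1894 matched and 1815 of these had the same version. The 79 without a match held 2 counts in replicate 1 and 5 in replicate 2. Positions of miRNA genes in exons or introns of other genes on the same strand were read from the same release, with an exon of any transcript taken as exonic.

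The sense column was used by a rule set before the data were examined, which takes the strand column with the larger total. Levels are given as CPM, read counts scaled to a common library total over the sense counts of all genes. A CPM of 1 was the detection limit, and 3 counts were taken as the floor for a gene with none, or 0.875 CPM in replicate 1 and 0.522 CPM in replicate 2. Means and standard deviations (SD) are over the 2 libraries. Intervals of shares are exact Clopper-Pearson intervals at 95%. Reads were not counted as independent molecules, so intervals, floors and the binomial test cover counting error only.

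Ratios between the libraries are replicate 2 over replicate 1 after TMM scaling of edgeR, on the log2 scale with a pseudocount of 1 CPM. The pseudocount understates ratios of genes with low counts. Single-gene ratios were tested with a two-sided conditional exact binomial test and Benjamini-Hochberg adjustment over the 717 genes with a count. That test compares these libraries, not conditions. A list was described by the median log2 ratio of its members with a mean CPM of at least 1, and by the percentile of that median among 10000 random lists of the same size matched on decile of expression. The biological coefficient of variation came from edgeR's dispersion estimate with an intercept-only design. Clusters were runs of genes on the same strand with gaps of at most 10 kb and at least 3 members at a mean CPM of at least 1. Their SD of log2 CPM was set against 10000 random gene sets of the same size, with a two-sided permutation p.

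Genes to be named were fixed before the data were examined as the 25 of highest mean CPM, up to 4 members of highest mean CPM in each list, and the 10 of largest absolute log2 ratio among those with a mean CPM of at least 100 and an adjusted p under 0.05. Other genes are named as members or ends of a cluster, as holders or partners of opposite-strand reads, or where they are said to lie outside the rule, and all of these were chosen after their values were seen. The 27 lists were fixed at the same time as miRNA numbers. RefSeq synonyms were added afterwards to match those numbers to symbols. By that match Mir92-1 and Mir92-2 were not taken as members of the list of the Mir17 cluster, and Gm25641 entered the progenitor list through a synonym. Lists share members.

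Numbered copies are genes whose symbol ends in a copy number. As an alternative, genes sharing at least 20 bases with another miRNA transcript of M21 were counted. The length of 20 bases was chosen after the files were read, and no genome sequence was used here. Other alternatives were the other count columns, other detection limits, pseudocounts of 0.1 and 10, filters on CPM, DESeq2 size factors, total counts, upper-quartile scaling, a fixed coefficient of variation of 10% in edgeR's exact test, cluster gaps of 5 kb and 50 kb, and leaving out each replicate.

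The procedures were tested on simulated counts for the same genes and library sizes. The binomial test recovered 97.6% of 1.5-fold changes among 85 changed genes with at least 100 counts, and 44.5% of all 200 changed genes. Of 1.2-fold changes it recovered 72% among 75 genes with at least 100 counts and 27% of all 200. Simulated coefficients of variation of 5%, 10% and 20% were estimated as 5.05%, 9.91% and 21.2%. All 5 planted clusters were called. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The signal tracks and alignments that the readme text lists were not used here.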

Results

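The data are 2 libraries of small RNA from embryonic mouse midbrain at 15.5 days, a stage of ongoing neuronal differentiation. The deposited tables list 7557669 reads for replicate 1, a pool of 78 embryos, and 13115314 reads for replicate 2, a pool of 62 embryos. Reads on the sense strand of miRNA genes numbered 3429704 (45.4%, 95% exact interval 45.3 to 45.4) in replicate 1 and 5752476 (43.9%, 43.8 to 43.9) in replicate 2, a ratio of 1.68. A single read was worth 0.292 CPM in replicate 1 and 0.174 CPM in replicate 2. No group other than midbrain was measured. The questions the design allows are therefore which miRNAs were counted, at what share of reads, and how closely the pools resembled each other. Intervals cover counting error only.

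Among reads assigned to a gene, Mir99a was by far the most counted miRNA of the midbrain, at 223432 ± 17520 CPM (SD, n = 2), or 22.3% of all sense counts. It was followed by Mirlet7g, a member of the let-7 family known for its part in the timing of differentiation, at 58849 ± 1630 CPM, and by Mir335, which lies in an intron of the imprinted gene Mest, at 57815 ± 5215 CPM. The SDs of those next 2 genes overlap, and their order differed between the libraries, with Mirlet7g at 60001 and 57696 CPM and Mir335 at 54127 and 61503 CPM in replicates 1 and 2. Mir99a exceeded Mirlet7g in counts by 3.80 times, far more than the spread between replicates. That spread cannot show a bias between miRNAs that both libraries share. Ranks here are therefore of counts. Mir100 (43170 ± 883.5 CPM), Mirlet7i (35852 ± 1916 CPM), Mir487b of the imprinted Dlk1-Dio3 region (30259 ± 4818 CPM) and Mir130a (28985 ± 1309 CPM) came next. Mir17 of the proliferation-associated Mir17 cluster had 25948 ± 1647 CPM and Mir99b 25936 ± 76.9 CPM, which were within their replicate spread of each other. Mir126a, an endothelial miRNA encoded within Egfl7, had 23238 ± 2362 CPM. These ranks leave out reads with several mapping places, which are given to no gene. Such reads were 0.83 and 0.82 times the sense gene reads in replicates 1 and 2, so miRNAs with copies may rank too low.

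The remaining 15 of the 25 highest genes fell from Mir149 at 22289 ± 1747 CPM and Mir30e at 21699 ± 2064 CPM to Mir181d at 8621 ± 728 CPM. Among them were Mir26b (16651 ± 1171 CPM), Mir181c (15010 ± 994 CPM), Mir369 (12903 ± 445 CPM), Mir93 (12531 ± 1004 CPM), the neuronal Mir137 (11192 ± 555 CPM), Mir135b (10648 ± 1458 CPM) and Mir30a (10429 ± 1093 CPM). Mir342, Mir30d, Mir20a, Mir127 and Mir23b lay between 8648 and 9836 CPM. In all, 8 genes made up 50% of the counts and 61 made up 90%. The 10 highest genes held 55.3% of counts and the 25 highest 74.0%, and 23 genes were among the 25 highest of both libraries. Detection at a CPM of at least 1 in both libraries was reached by 443 of 1973 genes, while 1256 had no count in either. A mean of at least 1000 CPM was reached by 92 genes and 10000 CPM by 19.

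**Figure D1:**
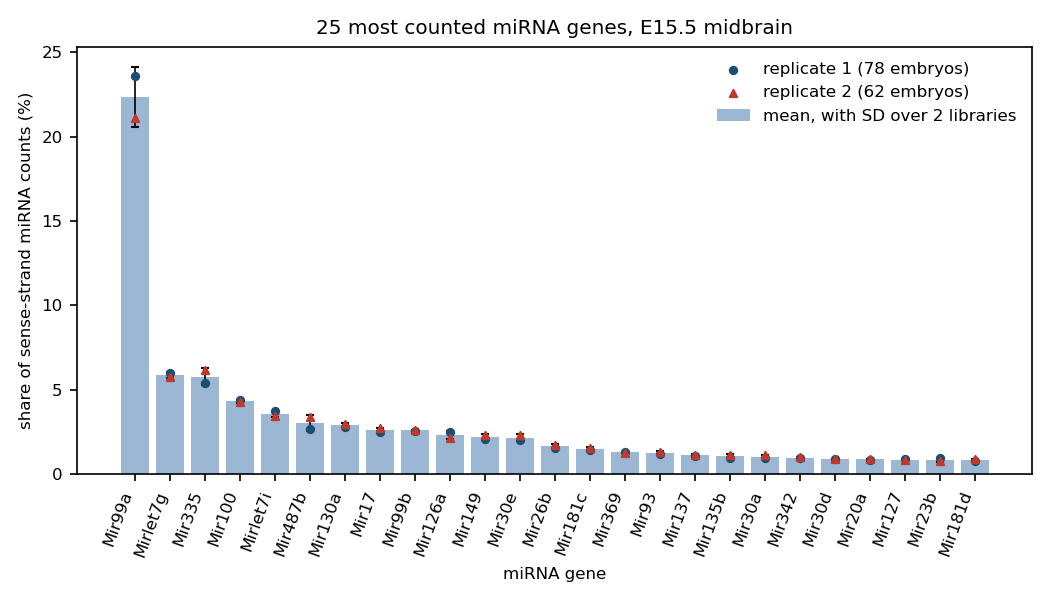
Share of sense-strand miRNA counts (%, vertical axis) of the 25 most counted miRNA genes (horizontal axis) in E15.5 midbrain. Bars are means with SD over 2 libraries, circles replicate 1 and triangles replicate 2. Mir99a holds 22.3% of counts, and Mirlet7g, the next, 5.88%.

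In the genome (mm10), Mir99a lies on chromosome 16 at 77598936 to 77599000, in an intron of the noncoding gene Mir99ahg. Mirlet7g is on chromosome 9 at 106178840 to 106178927 in an intron of Wdr82, and Mir335 on chromosome 6 at 30741299 to 30741396. Mir100 is on chromosome 9 at 41531425 to 41531504, in an intron of a noncoding transcript, and Mirlet7i on chromosome 10 at 122985640 to 122985724 in an exon of a transcribed pseudogene. Mir487b is on chromosome 12 at 109727333 to 109727414 and lies between annotated genes other than miRNAs, as does Mir130a on chromosome 2 at 84741115 to 84741178. Mir17 is on chromosome 14 at 115043671 to 115043754 in an exon of Mir17hg, Mir99b on chromosome 17 at 17830188 to 17830257 in an intron of Spaca6, and Mir126a on chromosome 2 at 26591357 to 26591429 in an exon of Egfl7. Of the 25 highest genes, 8 lie in exons of a host gene on the same strand, 13 in introns and 4 in neither.

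The list of Mir99a, Mir99b, Mir100 and the Mir125 genes held 30.3 ± 1.82% (SD, n = 2) of the counts, most of it Mir99a. It held 10.3% when Mir99a was left out of the counts. The let-7 family held 11.4 ± 0.492%. Mir125a had 6386 ± 149 CPM, far below its neighbour Mir99b. Within the let-7 family, Mirlet7d (6386 ± 641 CPM) and Mir98 (4392 ± 235 CPM) followed Mirlet7g and Mirlet7i. The Mir17 cluster and its paralogues held 6.05 ± 0.190%, led by Mir17, Mir93, Mir20a (8763 ± 51.7 CPM) and Mir106b (7735 ± 787 CPM). The imprinted Dlk1-Dio3 list held 9.68 ± 0.683%, led by Mir487b, Mir369, Mir127 (8661 ± 232 CPM) and Mir382 (7823 ± 832 CPM).

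The lists of neuronal miRNAs and of miRNAs of neural progenitors took nearly equal shares, 2.58 ± 0.129% and 2.60 ± 0.0284%, a gap smaller than the replicate spread. Replicate spread does not cover reads with several mapping places, which both shares leave out. Most of the progenitor share was Mir93 and Mir106b, which also belong to the list of the Mir17 cluster. The near equality therefore describes these lists and not the tissue. The neuronal list was led by Mir137, Mir153 (3360 ± 191 CPM), Mir7b (2648 ± 107 CPM) and Mir128-1 (1447 ± 62.5 CPM). The progenitor list was led by Mir93, Mir106b and Mir92b (4060 ± 22.2 CPM), followed by Mir9-3 (484 ± 39.7 CPM). The list of miRNAs associated with midbrain dopamine neurons held 2.17 ± 0.0875%, most of it Mir137, Mir7b, Mir125b-2 (2264 ± 50.3 CPM) and Mir125b-1 (2230 ± 47.2 CPM). Mir133b, also studied in dopamine neurons and named here outside the rule, had 1 count in replicate 1 and 0 in replicate 2, at or under the floor of 3 counts. Oligodendrocyte-lineage miRNAs held 0.175 ± 0.00874%, with Mir219a-2 at 1147 ± 110 CPM, Mir219a-1 at 331 ± 6.41 CPM and Mir338 at 271 ± 15.7 CPM. The list of miRNAs raised in maturing neurons held 0.0288 ± 0.00120%, with Mir29a at 165 ± 0.495 CPM, Mir29c at 119 ± 11.8 CPM and both Mir29b copies below 3 CPM.

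Of the blood vessel miRNAs, Mir126a and Mir143 were abundant. Endothelial Mir126a alone held 2.32 ± 0.236% of counts. The mural and smooth muscle list held 0.613 ± 0.0370%, nearly all of it Mir143 (6058 ± 373 CPM), against 72.3 ± 3.25 CPM for Mir145a and 0 counts for Mir145b. The astrocyte and glia list, which also contains Mir143, held 1.62 ± 0.154%, with Mir23a at 4225 ± 756 CPM, Mir21a at 3608 ± 300 CPM and Mir449a at 2197 ± 101 CPM. Its members are only weakly specific to glia. Mesenchymal miRNAs held 0.399 ± 0.00190%, led by Mir140 (3682 ± 14.2 CPM), the pituitary and endocrine list 0.416 ± 0.0256%, led by Mir7b and including Mir375 (434.1 ± 58.9 CPM), and the list of multiciliated cells 0.276 ± 0.0116%, led by Mir449a and Mir34c (544.4 ± 11.5 CPM). The list of choroid plexus and pigment epithelium held 0.133 ± 0.0258%, nearly all of it Mir204 (1313 ± 260 CPM), with Mir211 at 15.5 ± 1.55 CPM.

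Of the blood lists, that of white cells and microglia held 0.0326 ± 0.00105%, with Mir223 at 158 ± 4.32 CPM, Mir155 at 99.5 ± 3.24 CPM and Mir150 at 69.4 ± 2.94 CPM. With counts on either strand its share was 0.0532%, because reads opposite to its member Mir142b then came to 213 ± 11.96 CPM, above Mir223. That of red cells held 0.0203 ± 0.000764%, with Mir451a at 144.9 ± 11.5 CPM, Mir144 at 37.1 ± 5.26 CPM and Mir486 at 20.5 ± 1.43 CPM. Liver and gut miRNAs held 0.0226 ± 0.00147%, with Mir192 at 87.2 ± 2.08 CPM, Mir194-2 at 74.6 ± 9.13 CPM and hepatocyte Mir122 at 59.6 ± 23.3 CPM. Skeletal and cardiac muscle miRNAs held 0.00586 ± 0.00272%, led by Mir208b at 33.3 ± 20.3 CPM and Mir206 at 13.8 ± 3.06 CPM. Epithelial miRNAs held 0.0730 ± 0.0104%, led by Mir203 at 601 ± 47.2 CPM, and the sensory list (Mir182, Mir183 and Mir96) 0.163 ± 0.0315%. The Hox list held 0.124 ± 0.0335%, the pluripotent stem cell list 0.0952 ± 0.0146% with Mir302a at 378 ± 53.2 CPM, and the Sfmbt2 list 0.455 ± 0.0225% with Mir467c, Mir467e and Mir467d at 1280 ± 38.3, 1268 ± 118 and 1241 ± 96.8 CPM. The Mir467 genes share sequence with other miRNAs, so their levels are uncertain. The X-linked testis list held 0.000110 ± 0.000115% of counts, 1 count of Mir741 in replicate 1 and 9 in replicate 2 being most of it. Mir6236, the only matched member of the list of ribosomal or small nucleolar fragments, held 0.00483 ± 0.000151%.

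**Figure D2:**
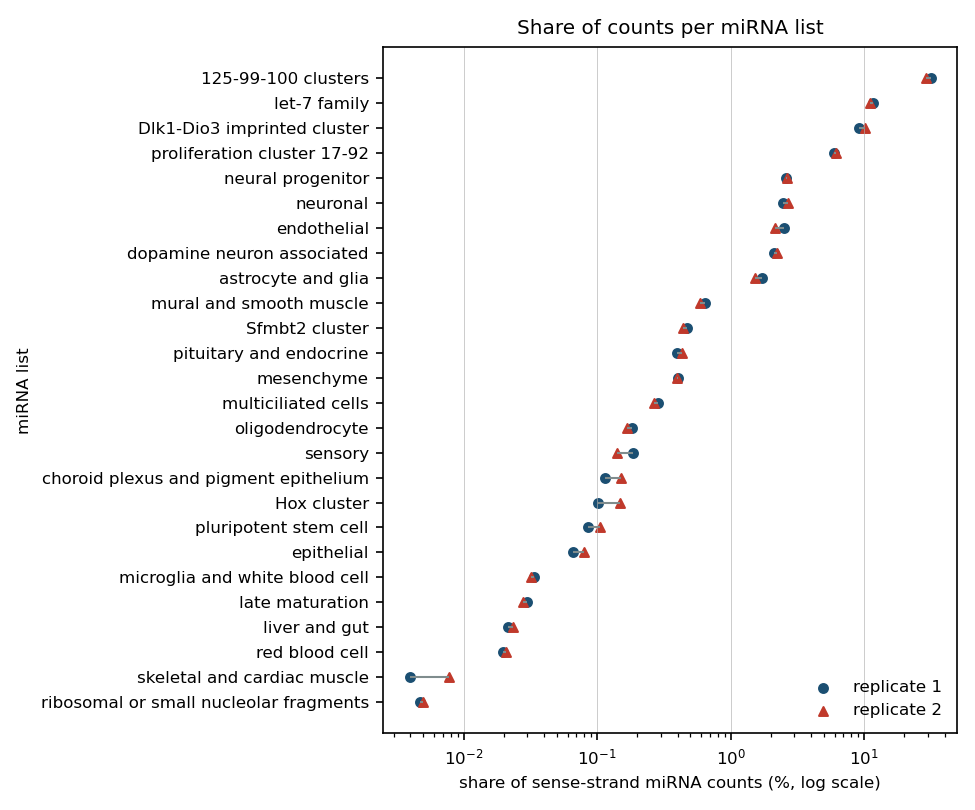
Share of sense-strand miRNA counts (%, horizontal log axis) of each miRNA list (vertical axis), with circles for replicate 1 and triangles for replicate 2 joined by a line. The shares run from 30.3% for the list of Mir99, Mir100 and Mir125 genes to 0.00483% for ribosomal or small nucleolar fragments. The testis list, lower still, is not drawn.

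The pools gave closely similar profiles. Of the genes with a mean of at least 100 CPM, 99.01% lay within 1.5-fold of equal levels, and 1, Mir181a-2, was more than 2-fold apart. Across the 474 genes with a mean of at least 1 CPM, Pearson's r of log2(CPM + 1) was 0.995 and Spearman's rho 0.983. Both are across genes, which are not independent replicates. The median absolute log2 ratio was 0.16, a fold of 1.12, and edgeR's biological coefficient of variation was 10.2%. The labels describe separate pools, and the counts differed by more than counting noise (chi-square 27185 on 468 degrees of freedom), which tells apart repeated deposits of a library but not repeated libraries of the same RNA. DESeq2 gave a coefficient of variation of 45.8% with a mean fit and 1.33% as the median of its gene estimates.

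**Figure D3:**
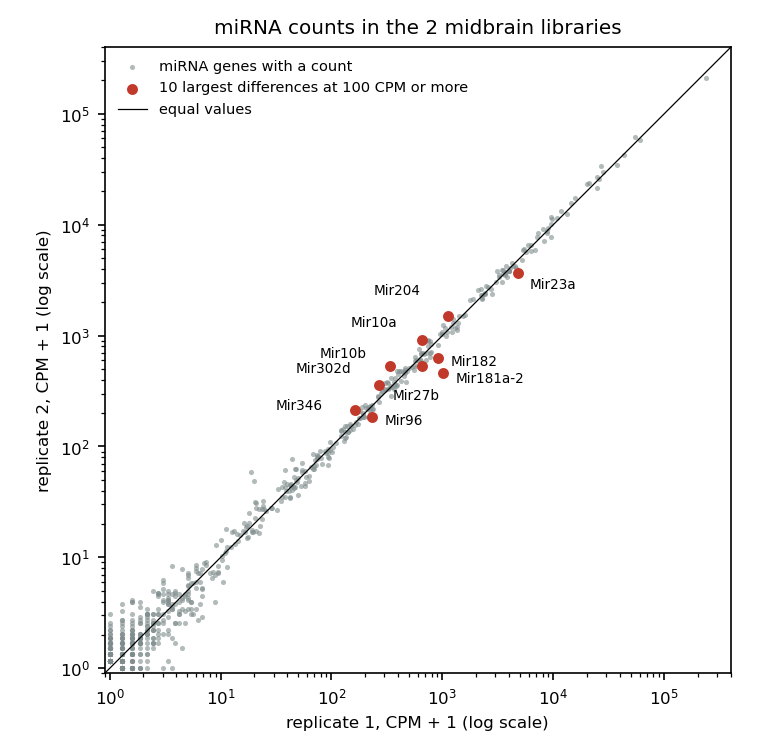
CPM + 1 in replicate 1 (horizontal log axis) against replicate 2 (vertical log axis) for each miRNA gene with a count in either library. Red points are the 10 genes of largest ratio among those of at least 100 CPM that passed the exact binomial test, and the line marks equal values. Mir181a-2 lies below the line at 1015 CPM in replicate 1 and 461 CPM in replicate 2.

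Between the pools, Mir10b and Mir10a of the Hox clusters were higher in replicate 2, while Mir181a-2, the sensory Mir182 and Mir96, and the Mir23 genes were higher in replicate 1. Mir181a-2 had the largest ratio among genes of at least 100 CPM, at 1015 CPM in replicate 1 and 461 in replicate 2 (log2 ratio -1.17, 95% counting interval -1.24 to -1.10). It is a numbered copy that shares sequence with other miRNAs, so its level is uncertain. Mir10b had 339 and 532 CPM (log2 ratio 0.62), Mir10a 649 and 917 CPM (0.46), Mir302d 264 and 354 CPM (0.39), Mir204 1129 and 1497 CPM (0.37) and Mir346 162 and 214.2 CPM (0.37). Higher in replicate 1 were Mir182 (907 and 628 CPM, log2 ratio -0.56), Mir23a (4760 and 3690 CPM, -0.40), Mir96 (231 and 183.1 CPM, -0.37) and Mir27b (653.7 and 528 CPM, -0.34). The adjusted p in the conditional exact binomial test ranged over these 10 genes from 9.60e-218 for Mir181a-2 to 3.47e-06 for Mir346. Of 717 genes tested, 70 were higher in replicate 2 and 72 higher in replicate 1 beyond counting error. With a coefficient of variation of 10% allowed for, edgeR's exact test kept 3, namely Mir205 (3.07-fold higher in replicate 2), Mir208b (2.38-fold) and Mir181a-2 (0.445-fold for replicate 2 over replicate 1). With 1 library per pool, no difference between the pools has a replicate check.

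Lists for muscle, Hox, epithelial and liver and gut miRNAs had median ratios toward replicate 2, and let-7, astrocyte and glia, sensory and Sfmbt2 lists toward replicate 1. These 8 of 24 lists lay outside the central 95% of matched random lists, where 1.2 would be expected if genes and lists were independent. Genes and lists are not independent here, since lists share members and some, such as the sensory list, hold genes of the same cluster. The excess over 1.2 is therefore not a test. Of the Hox list (median log2 ratio 0.60, percentile 99.6), 3 of 5 members were higher in replicate 2 by the exact binomial test, namely Mir10a, Mir10b and Mir196b (0.60), and 3 adjusted over the list alone. Of the epithelial list (0.65), 3 of 7 were higher in replicate 2 and 4 adjusted over the list alone, with Mir205 at 17.8 and 57.9 CPM and Mir429 at a log2 ratio of 0.65. Of the muscle list (0.62, percentile 99.8), 1 of 8, Mir208b (18.95 and 47.6 CPM), was higher, and 1 adjusted over the list alone. The muscle median rests on 4 members, and with the 2 of at least 10 CPM it was 0.82 (percentile 97.7). Its members Mir1a-1, Mir133a-1 and Mir133a-2, named outside the rule, had 0 counts. The liver and gut list (0.74) had 1 of 5 higher, Mir122 at 0.77, and adjusted over the list alone 1 higher and 1 lower. Its median rests on members with few counts and was -0.081 among the 3 members of at least 10 CPM. With a pseudocount of 10 the medians were 0.30 for the epithelial list, 0.27 for muscle and 0.19 for liver and gut, all still outside the central 95%.

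In the other direction, 7 of 10 let-7 family members were higher in replicate 1 (median log2 ratio -0.14, percentile 1.77) and 8 adjusted over the list alone, including Mirlet7g (-0.090), Mirlet7i (-0.14) and Mirlet7d (-0.24). All 3 sensory genes were higher in replicate 1 (median -0.37, percentile 0.295), as they were adjusted over the list alone. Of the astrocyte and glia list (-0.20, percentile 1.22) 5 of 6 were higher in replicate 1, with Mir21a at -0.20, and 5 adjusted over the list alone. The Sfmbt2 list (-0.18, percentile 1.15) had 5 of 67 higher in replicate 1, and 5 adjusted over the list alone. Only 10 of its members reached a mean of 1 CPM, and most others had no count. Its median left the outer range without a filter (-0.14, percentile 3.35). Its members Mir467c, Mir467e and Mir467d share 31, 29 and 41 stretches of 20 bases with other miRNA transcripts, so their levels are uncertain. Endothelial Mir126a was also higher in replicate 1 (log2 ratio -0.24). The exact binomial test called most genes of at least 100 CPM in one direction or the other (116 genes). All let-7 and sensory members lay above that level. Member counts of lists, toward either replicate, therefore partly reflect depth and do not by themselves show a shift of a list. No let-7, sensory, astrocyte and glia or Sfmbt2 member was higher in replicate 2 by that test.

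Several well known brain miRNAs with numbered copies in the genome had low counts, while other copies were abundant. Mir124a-1, Mir124a-2 and Mir124a-3, copies of a neuronal miRNA that is among the most abundant of mature brain, had 3.69 ± 0.551, 3.26 ± 1.17 and 0.552 ± 0.0436 CPM, and Mir9-2 had 1.66 ± 0.131 CPM against 484 for Mir9-3. These were named outside the rule, after their values were seen. The 121 numbered copies together held 2.99 ± 0.0535% of counts. Of the 92 genes with a mean of at least 1000 CPM, 10 were numbered copies, such as Mir125b-2, Mir128-1 and Mir219a-2, and of the 50 highest genes 1 was. Of these copies, 120 share at least 20 bases with another miRNA transcript. Reads with several mapping places, which are given to no gene, made up 43.5% and 43.1% of mapped reads in replicates 1 and 2. Levels of Mir124, Mir9 and other copied miRNAs are therefore uncertain in these counts, and neuronal and progenitor shares leave out those reads.

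The longest of 3 runs of clustered miRNAs in the Dlk1-Dio3 region stood closer together in level than random miRNAs of at least 1 CPM, but not than random miRNAs of at least 10 CPM. The run of 30 genes from Mir379 to Mir3072 on chromosome 12, at 109709060 to 109747960, held 7.64% of counts and had an SD of log2 CPM of 2.78, against a median of 4.16 in random sets (adjusted permutation p 0.0102, two-sided). Even so, Mir487b exceeded the lowest member by 2669 times. It was the only one of 17 clusters to pass. The region's runs around Mir127 (11 genes, SD 3.31 against 4.13) and around Mir370 (3 genes, 3.77 against 3.74) had adjusted permutation p of 0.608 and 0.984. The Mir17 cluster (SD 4.58 over 6 genes, against 4.06 in random sets) did not pass. Nor did the Mir302 cluster (1.55 over 4, against 3.96) or the sensory Mir182 cluster (1.03 over 3, against 3.74). Their adjusted permutation p were 0.874, 0.412 and 0.412. In proportion, the Mir302 and Mir182 clusters lay further below random sets than the run that passed. With 3 members, even an SD of 0.64 in the Mir293 cluster gave an unadjusted permutation p of 0.0548. Passing therefore partly reflects the number of members. With members and random sets of at least 10 CPM, 0 of 12 clusters passed. The run of 30 genes was then the same, with the same SD, but random sets had a median of 3.01 (permutation p 0.475, adjusted 0.806), so its closeness to random miRNAs rests on including genes of 1 to 10 CPM among them.

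Nearly all counts lay on the annotated strand of their gene. Counts on the opposite strand were 2.23% of gene reads in replicate 1 (95% exact interval 2.21 to 2.24) and 2.36% in replicate 2 (2.34 to 2.37). Of them 99.8% fell on 11 genes with a mean of at least 100 counts over both strands, and each of these 11 had over 50% of its counts there. Mir142b, which lies opposite to the white cell gene Mir142, had 0 sense counts in both libraries, so sense counts give the white cell list no value for that locus.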

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

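The tests of opposite-strand reads in this part were chosen after the result was seen. Reads lay on the strand opposite to 11 genes at levels well above the limit that a count of 0 allows, in a column that the levels reported above do not use. The mean counts over both libraries were 27541 for Gm24321, 26378 for Gm25927, 18670 for Gm25252, 14612 for Gm24083, 11887 for Gm25301, 3115 for Gm25750, 2646 for Mir299b, 1871 for Mir497b, 993 for Mir142b, 366 for Gm24111 and 124.5 for Gm25641. In annotation M21, the strand those reads match carries Mir409, Mirlet7e, Mir376a, Mir191, Mir378a, Mir380, Mir299a, Mir497, Mir142, Mirlet7f-1 and Mir9-1, in that order.

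Imperfect strand marking of the libraries was argued against, since the other genes of at least 100 counts had 0.0046% of their counts on the opposite strand. A candidate explanation is that the miRNA on the other strand was absent from the count table, so that its reads were tallied only against the gene facing it. For all 11 genes the M21 partner was absent from the table, and 27 genes of that depth have an absent partner in all. No gene of that depth has a partner in the table, so a present partner could not be compared. No biological explanation was tested, since the design gives none.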

How the results depend on the processing

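Among alternatives, a limit of 100 CPM for differences between the libraries, which stayed within 1.5 times the main count, and the median of DESeq2's gene estimates were chosen after the data were seen. No paired analysis was possible because there is 1 group. Detected genes (306 to 589 over 5 detection or column settings other than the opposite strand), strand calls (11 or 12) and differences beyond counting error (up to 147 with other scalings, filters and the unstranded column) stayed within 1.5 times. Leaving out each replicate gave 464 to 483 detected genes, 60 to 61 genes for 90% of counts, and 54.7% to 56.1% for the 10 highest. Replicate agreement has no value without a replicate. With the opposite-strand column, which holds few reads, values were 33 detected genes, 5 genes for 90% of counts, 99.7% for the 10 highest, r 0.854, rho 0.674, median absolute log2 ratio 3.07, 3 differing genes and 1 list of at least 1% of counts. The unstranded column gave 54.1% for the 10 highest, and 118 of list shares and named-gene levels moved by less than 1 SD and 13 by more. Pearson's r was 0.987 with a pseudocount of 0.1, 0.998 with 10 and 0.997 at 100 CPM or more. Spearman's rho was 0.949 without a filter and 0.994 at 100 CPM or more. The median absolute log2 ratio was 0.18 and 0.12 with pseudocounts of 0.1 and 10, 0.23 without a filter and 0.12 at 100 CPM or more; the cause was not tested. DESeq2 put the coefficient of variation at 45.8% with a mean fit and 1.33% as a median, and the cause was not tested. A fixed 10% variation left 3 differing genes, since that test allows for more than counting error. Genes sharing 20 bases held 9.47% of counts, a wider class than numbered copies. At 10 CPM or more 0 clusters were called; the run called before kept its members, and random sets lost genes of 1 to 10 CPM. The liver and gut list reversed to -0.081 at 10 CPM or more, where 3 members remain. The stem cell list passed the outer bound without a filter (0.23) and with a pseudocount of 10 (0.23), and the Sfmbt2 list lost it without a filter (-0.14); the cause was not tested. Without Mir99a the list holding it had 10.3% of counts and the let-7 family 14.7%, by the smaller total. Depth limits genes near 1 CPM, where a library has 3 to 6 reads.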

Other observations

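The tests of copies, of Hox miRNAs and of shared differences within clusters in this part were chosen after the results were seen, although the fixed variation of 10% was set before the data were examined. Members of a cluster reached very different levels. Mir449a of the multiciliated cell list had 2197 CPM, 1238 times its lowest neighbour, Mir449b. In the Mir17 cluster the highest gene, Mir17, exceeded the lowest, Mir19b-1, by 3539 times, although Mir19b-1 is a numbered copy that shares sequence with others, so its level is uncertain. Mir93 exceeded Mir25 by 33.97 times. The sensory genes stood closer, with Mir182 3.71 times Mir96. Mir181c and Mir181d, which lie together in an intron of Nanos3, had 15010 and 8621 CPM. Mir181a-2, with a log2 ratio of -1.17 between the pools, is a neighbour of Mir181b-2, whose log2 ratio was 0.15, and its copy Mir181a-1 had -0.027. Mir449b, Mir19b-1, Mir25, Mir181b-2 and Mir181a-1 lie outside the rule for named genes and were chosen after their values were seen.

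Some miRNAs read only against a facing gene had many reads and others few. On the scale of counts on either strand, the reads at Mir409 came to 5711 ± 833 CPM (SD, n = 2), at Mirlet7e to 5609 ± 22.5 CPM, at Mir376a to 3977 ± 22.3 CPM, at Mir191 to 3102 ± 38.7 CPM and at Mir378a to 2523 ± 37.1 CPM. The other 6 were lower, with 654.98 CPM at Mir380, 566 at Mir299a, 406 at Mir497, 213 ± 11.96 at the white cell gene Mir142, 78.2 at Mirlet7f-1 and 25.4 at Mir9-1. Those reads lie on the opposite strand of the counted genes. The sense shares of the let-7, Dlk1-Dio3, white cell and neural progenitor lists therefore leave them out.

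Numbered copies of miRNAs had low counts next to relatives without a copy number. In 17 of 17 families the highest unnumbered member exceeded the highest copy. The same held in 12 of 12 families when unnumbered members with shared sequence were left out. The highest copies in those 12 families still shared sequence, so this describes the pattern and does not test a cause. Whether the copies' loci are little transcribed was left undecided. Against cluster neighbours without shared sequence, copies lay at a median of -5.42 on the log2 scale, with 19 of 19 below. Unnumbered genes without shared sequence lay at -0.65, a difference of -4.77. Only unnumbered genes served as neighbours, so they were set against each other while copies never were. Part of the difference is therefore built in. Unnumbered genes also spread widely, with Mir143 at 6.39 and Mir145a at -6.39. The comparison also holds only as far as cluster neighbours share a transcript. The same comparison with all unnumbered genes, some of which share sequence, was made first and gave -4.73 (two-sided permutation p 0.00064). A candidate explanation is that reads with several mapping places were not counted. Unnumbered genes with shared sequence also lay lower against their neighbours than those without, by a median of -3.18 (two-sided permutation p 0.0212). However, only 6 of 11 such genes lay below their neighbours. Most of the 11 shared only 1 or 2 stretches of 20 bases, such as Mir302a, Mir302b and Mir487b with 1 each. So short a match need not span a whole read, so the comparison bears little on this explanation. Mir3070a and Mir3070b (28 each) and Mir376c (12), named outside the rule, shared more and lay at -8.11, -10.7 and 0.22. The permutation treated genes as independent, but several of the 11 lie in the same cluster, such as Mir302a and Mir302b, so its p is likely too small. Differences in processing or stability between copies remain open and were not tested.

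The Hox-cluster miRNAs Mir10a, Mir10b and Mir196b were higher in replicate 2. More non-neural tissue in replicate 2 stays open, because 3 of 7 non-neural lists (epithelial, muscle, and liver and gut, the last only with its members under 10 CPM) lay above the central 95% while 3 others (mesenchyme, mural, and white cells) had medians under 0, and endothelial Mir126a, a list of 1 gene and so without a percentile, had a log2 ratio of -0.24. The muscle median rested on 4 members, of which Mir208a and Mir499 were under 10 CPM. By the exact binomial test 1 of 8 members of the muscle list and 1 of 5 of the liver and gut list were higher in replicate 2. Ordinary spread between pools may account for single genes, as the lowest adjusted p of Mir10a and Mir10b in edgeR's exact test with a coefficient of variation of 10% was 0.275. A different dissection border between the pools stays open and was not tested.

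A hypothesis that members of a cluster differ together between the pools was left undecided. The pooled SD of log2 ratios within 17 clusters was 0.31 against a median of 0.35 in 2000 matched random sets (one-sided permutation p 0.241).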
